A study of Rattus norvegicus with 19 samples.

How the data were processed

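Single T11 dorsal root ganglia of 19 rats were measured, 5 naive, 7 at day 7 and 7 at day 14 after surgery, with 1 array per rat. Per the labels' protocols, RNA of each ganglion went through 2 rounds of linear amplification before hybridisation, which can shift the balance of 3' and 5' signal. Per the labels, 1 further naive array was removed by the submitters after their quality control, and it is not analysed here. The deposited values are log2 expression levels per probe set, and per the submitters' processing notes the authors used RMA, which corrects background, quantile-normalizes arrays and summarises probes, and limma. Versions of these are not given in the sources used here. Because RMA forces a common distribution on all arrays, a shift of most transcripts in one direction would be hidden.

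The table held 31099 probe sets. The 57 control probe sets were left out of all tests, leaving 31042. Gene names came from the platform annotation, updated through gene identifiers for 20758 probe sets and through accessions for 2, while 66 kept their name, and 1 symbol changed. The update used RefSeq gene names of assembly GRCr8. In all 20826 probe sets carried 1 gene symbol, 436 several and 9780 none, and 14217 genes had at least 1. Probe sets with several symbols were not named. No pair of arrays held identical values, and correlations between arrays lay between 0.987 and 0.997.

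Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on all 3 groups in 1 fit, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Moderation gave 4.20 prior degrees of freedom beside 16 residual ones. Lists were tested with camera at a preset correlation of 0.01 on 1 probe set per gene, the one with the highest mean, for 30 lists of at least 5 measured genes. Of 829 listed genes 712 were measured. A list test asks whether a list moves relative to other genes. Exact permutation tests were two-sided and used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.

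Groups, tests, lists and alternatives were fixed before the data were examined, except those named as chosen later, as was the rule for named genes. The rule named the 12 largest rises and falls past the threshold with 1 gene symbol, filled to 5 per direction by the smallest p where fewer passed, then up to 4 members of each list that passed, a fixed set of genes of nerve injury and neurotrophin signalling, and any member past the threshold of a list with 3 or fewer such members. Alternatives covered a filter on dim probe sets, renormalization, moderation, array weights, the samples in the fit, the unit of test, blocks and covariates, set tests, thresholds and leaving out each array. The letters that begin each animal code in the labels (AI, AJ or AK) were used as a block, although the labels do not say what they mean.

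The tests were checked on simulated data made from the residuals of these arrays, with whole arrays shuffled, with 200 changed probe sets among 31042. For day 14 against naive, 74.5% of changes of 0.5 log2 units were recovered, 98% of changes of 1 and 100% of changes of 2, with 0 to 3 false calls. For day 7 against naive 77.5%, 98% and 99.5% were recovered with 2 to 7 false calls, and for day 14 against day 7 85.5%, 97.5% and 100% with 2 to 66. Each simulated change was the same on every array of the group. Recovery of changes that differ between rats is therefore not shown, and such changes can be missed even where large. Lists of 25 genes shifted by 0.3 log2 units were found in 9 of 9 runs, with 0 of 261 other lists past the threshold. These simulated lists held genes drawn at random, so they do not show how camera fares with lists of genes that vary together.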

Results

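The transcriptome of the T11 dorsal root ganglion, which holds the cell bodies of the sensory neurons of one thoracic segment, was profiled in adult female Sprague-Dawley rats. The cutaneous nerves of the neighbouring segments T9, T10, T12 and T13 had been cut on one side, which leaves the T11 skin nerves intact beside denervated skin and induces them to sprout collaterally. Each rat gave 1 Affymetrix expression array of the rat genome. The data comprised 5 unoperated (naive) rats, 7 rats at day 7 and 7 rats at day 14 after surgery, 19 arrays in all. The study presumed day 7 to represent the initiation and day 14 the maintenance of sprouting. Naive rats had no operation, so surgery as such and denervation of the neighbouring skin were not separable. All 31042 probe sets other than controls were tested, on log2 values between 3.48 and 14.02. The arrays carry no read depth, and their number limits the precision: the median standard error of a log2 difference from naive was 0.080.

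The first comparison asked what differs in the ganglion during the presumed initiation phase. At day 7 no single transcript passed the threshold. The largest list difference was in genes of the nerve injury response, with Npy, a neuropeptide induced in injured sensory neurons, 2.49 ± 0.78 (SE) log2 units above naive. Transcripts of myelinating Schwann cells, such as Mag, a myelin adhesion protein, lay below naive as a list. Both list differences rest on a preset correlation and were lost with an estimated one (adjusted p = 0.998 for each). With limma, 0 of 31042 probe sets passed an adjusted p of 0.05. At an unadjusted p under 0.05 there were 2700, of which 1147 were higher and 1553 lower, where 1552 would be met by chance. The smallest adjusted p was 0.143.

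Among the probe sets with the smallest p at day 7, none past the threshold, Bdnf, the neurotrophin brain-derived neurotrophic factor, averaged 8.73 ± 0.31 (SD, n = 7) against 7.94 ± 0.30 (SD, n = 5) in naive rats. Its log2 difference was 0.79 ± 0.16 (SE), with a limma adjusted p of 0.176, and 6 of 7 arrays lay above the highest naive array. Bdnf passed adjusted over the list alone, for both the neurotrophin and the repair Schwann cell list. The other rises of smallest p were Nppa, Slc41a2, Txnrd1 and Copz1, at 0.30 to 0.41, and Slc41a2 and Nppa had a smaller p than Bdnf. Other probe sets stood at 0.02 for Slc41a2, 0.30 for Txnrd1 and 0.07 for Copz1. In the other direction stood Grhl3 at -1.03, Ccdc127 at -0.76, Nherf4 at -0.38, Rpl37-ps2 at -0.37 and Abca8a at -0.28. All 7 day 7 arrays lay below every naive array for Ccdc127, Nherf4, Rpl37-ps2 and Abca8a.

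Of the 30 gene lists fixed in advance, 4 passed limma's camera test with a preset correlation at day 7. The nerve injury response list was higher by a mean of 0.47 log2 units, with 26 of 30 members above naive (adjusted p = 3.9e-06). It missed with an estimated correlation (adjusted p = 0.998). Adjusted over the list alone, 3 members passed, Cacna2d1 (0.63), a calcium channel subunit, Gadd45a (0.76), a stress-response gene, and Npy, against 0 over all genes tested. The myelinating Schwann cell list was lower by a mean of -0.25, with 16 of 18 members below naive (adjusted p = 4.4e-06). With an estimated correlation its adjusted p was 0.998. Fa2h (-0.38), Mag (-0.51) and Bcas1 (-0.41) passed adjusted over the list alone, and Sox10 stood at -0.31. The extracellular matrix and fibroblast list was lower by a mean of -0.10 in 29 of 36 members (adjusted p = 0.012, and adjusted p = 0.998 with an estimated correlation). Within it Col1a1 stood at -0.48, Col4a1 at -0.48, Col4a2 at -0.41 and Col1a2 at -0.28, with no member past adjusted over the list alone. The mitochondrial oxidative phosphorylation list was higher by a mean of 0.04 in 29 of 44 members (adjusted p = 0.032, and adjusted p = 0.998 with an estimated correlation). Its members went both ways, from Ndufb8 at 0.16, Sdhb at 0.15 and Ndufs7 at 0.15 to Ndufb5 at -0.18. The mean of this list turned to -0.01 with the 3' to 5' signal of control transcripts as a covariate. The number of lists was not above chance: 94 of 100 splits of the same arrays, the real one included, called at least 4.

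The second comparison asked what differs during the presumed maintenance phase. At day 14 Bdnf was higher than in naive rats by 0.83 ± 0.16 (SE) log2 units, a fold of 1.78. Its mean was 8.77 ± 0.29 (SD, n = 7) against 7.94 ± 0.30 (SD, n = 5), with a limma adjusted p of 0.038 and 6 of 7 arrays above every naive array. A second Bdnf probe set stood at 0.33. Copz1, a subunit of the vesicle coat that returns cargo to the endoplasmic reticulum, rose by 0.42 ± 0.06 (SE), Pde7b, a cyclic AMP phosphodiesterase, by 0.34 and Kif16b, an endosomal kinesin, by 0.36. The other Copz1 probe set, with a higher mean level of 11.5, stood at 0.04, and those of Kif16b stood between -0.11 and 0.05. Zc3h14 stood at 0.24 and missed the threshold (adjusted p = 0.053), with other probe sets at -0.03 and -0.04.

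Of the probe sets that passed at day 14, more fell than rose. Ccdc127 fell by 0.83 ± 0.14 (SE) and its other probe sets stood at -0.69 and -0.39. Grxcr1 fell by 0.82 and Mzf1 by 0.72. Bbs4, a component of the BBSome complex of primary cilia, fell by 0.71 ± 0.11 (SE), Bbs5, another component, by 0.41, Ift70a1, an intraflagellar transport gene, by 0.45 and Kifap3, an accessory subunit of kinesin-2, by 0.48. Patz1, Rpl37-ps2, Rasgrp2, Zfp157 and Sstr1, a somatostatin receptor, fell by 0.39 to 0.49. Other probe sets of Sstr1, Mzf1 and Patz1, and 1 of Kifap3, lay slightly above naive, at 0.02 to 0.18. Others stood at -0.13 for Bbs4, -0.30 for Rasgrp2 and -0.06 for Zfp157. In all, 43 of 31042 probe sets passed at day 14 with limma, 8 higher and 35 lower. Of these, 26 carried 1 gene symbol, 4 higher and 22 lower, and 17 were unnamed. Their log2 differences ran from 0.25 to 2.22 in size, and 1 exceeded a fold of 2. At an unadjusted p under 0.05 there were 6101, of which more were higher (3372) than lower (2729). The number was 0 with the prefix of the animal code as a block, where prefix AI occurred at day 14 alone, and 0 with the 3' to 5' signal as a covariate, and Bdnf then stood at 0.66 and 0.70. It was 401, 28, 5 and 15 without naive replicates 1, 2, 3 and 5, and 65, 26, 6 and 16 without day 14 replicates 1, 2, 5 and 6.

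The nerve injury response list was also higher at day 14, by a mean of 0.62 in 25 of 30 members (camera adjusted p = 2.6e-05). The call was lost with an estimated correlation (adjusted p = 0.786). Adjusted over the list alone, 10 members passed, against 0 over all genes tested. They included Npy (2.98), Vip (2.89) and Gal (1.46), which encode neuropeptides, Atf3 (1.62), a transcription factor of injured neurons, and Sprr1a (1.43), Gadd45a (0.94), Cacna2d1 (0.65) and Jun (0.39). Rats differed widely in these genes: Atf3 was 8.16 ± 0.18 (SD, n = 5) in naive rats, 9.04 ± 1.40 (SD, n = 7) at day 7 and 9.78 ± 1.28 (SD, n = 7) at day 14. The list also holds Csrp3 (3.04), a gene expressed in muscle and named here after its value was seen. Skeletal muscle transcripts were high on 1 array of each group, and the highest of these was naive (8.59). The skeletal muscle list stood at a mean of -0.30 at day 14 against naive, the opposite direction to Csrp3.

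**Figure D1:**
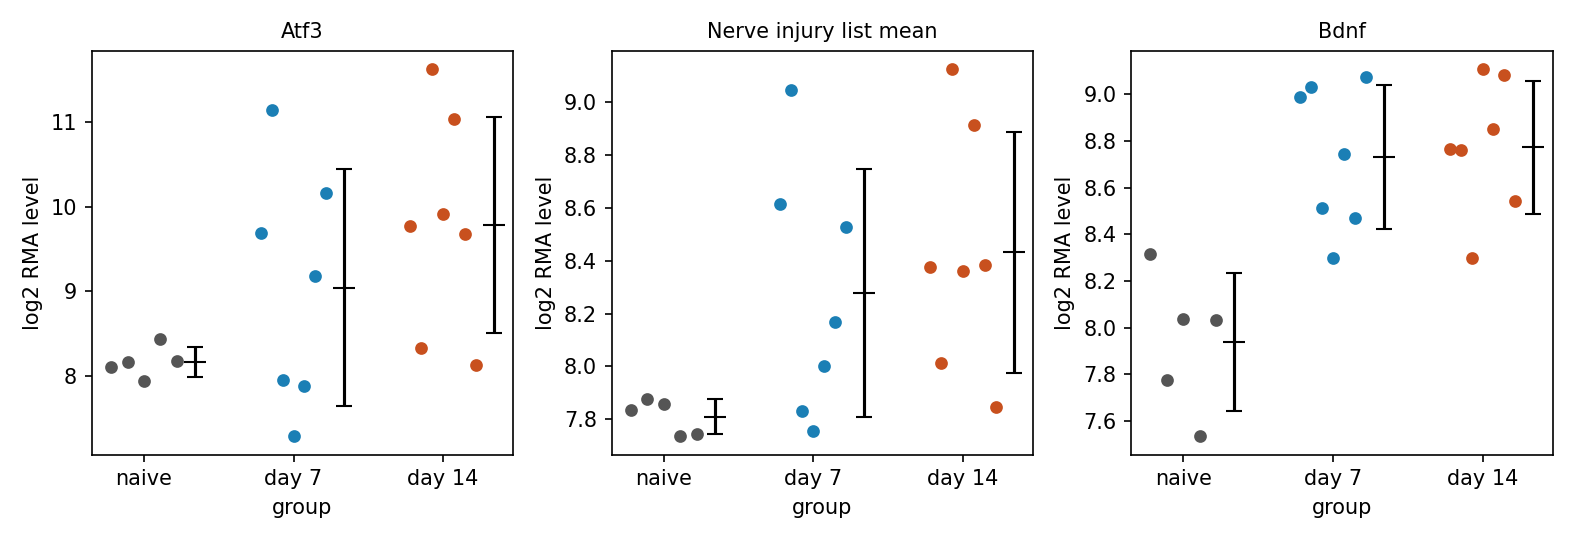
Log2 RMA level (vertical axes) of Atf3, the mean of the 30 nerve injury response genes, and Bdnf on each array (points) of the naive, day 7 and day 14 groups, with the group mean and SD (bars). Atf3 spans 7.28 to 11.15 at day 7 against 7.94 to 8.44 in naive rats, whereas 6 of 7 arrays of each operated group lie above every naive array for Bdnf.

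Immune and repair lists made up the rest of the day 14 differences, and 5 of 30 lists passed in all. The cytokine, chemokine and complement list was higher by a mean of 0.18 in 25 of 28 members (camera adjusted p = 1.1e-04, lost at an adjusted p = 0.183 with an estimated correlation). Ccl2, a monocyte chemoattractant, stood at 0.80, Ccl7 at 0.41, Il1a at 0.25 and Cd59b at 0.24, and 2 members passed adjusted over the list alone. The repair Schwann cell list was higher by 0.15 in 17 of 20 members (adjusted p = 0.0085, lost at an adjusted p = 0.336 with an estimated correlation). Bdnf was its single member past the threshold over all genes tested, and also the single one of the neurotrophin list, while Btc, Cdh2 and Olig1 stood at 0.16 to 0.17. The macrophage list was higher by 0.19 in 24 of 26 members (adjusted p = 0.0085, lost at an adjusted p = 0.899 with an estimated correlation), with Fcgr3a at 0.45, Laptm5 at 0.44, Ctss at 0.41 and Trem2 at 0.21. The MHC and antigen presentation list was higher by 0.27 in 17 of 21 members (adjusted p = 0.0085, lost at an adjusted p = 0.899 with an estimated correlation). Its class II genes RT1-Db1 and Cd74 stood at 0.85 and 0.83, RT1-Da at 0.56 and the peptide transporter Tap2 at 0.31. After adjustment over the 30 lists, 0 lists passed with an estimated correlation in any of the 3 comparisons. With fry, another set test of limma, 2 lists passed at day 14. These were the cytokine, chemokine and complement list (fry adjusted p = 0.012) and the repair Schwann cell list (fry adjusted p = 0.026). The nerve injury response, macrophage and MHC lists did not pass fry. As many as 5 lists were called in 78 of 100 splits of the same arrays, the real one included.

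Several gene groups linked to growth and to pain did not pass at day 14. The growth cone and axon cytoskeleton list averaged 0.06 above naive (camera adjusted p = 0.167), the neurotrophin and GDNF-family list 0.01 (adjusted p = 0.709) and the peptidergic nociceptor list 0.10 (adjusted p = 0.305), while the nonpeptidergic nociceptor list stood at -0.07 (adjusted p = 0.225). The interferon response list stood at -0.01 (adjusted p = 0.889). Gap43, a growth cone protein, differed from naive by 0.03 ± 0.06 (SE) at day 7 and by 0.09 ± 0.06 at day 14. Sox11 stood at 0.14 and 0.12, at a low mean level of 4.78 in naive rats. Cd2ap stood at -0.06 and -0.05, and the neurotrophin receptors Ngfr at 0.02 and 0.05 and Ntrk2 at -0.04 and 0.00. Csf1 stood at 0.03 and 0.08 and Calca, which encodes a pain-related peptide, at 0.02 and 0.07. Other Calca probe sets, with lower mean levels, stood at 0.46 and 0.09 at day 7 and at 0.39 and 0.18 at day 14. Tac1 stood at 0.37 and 0.20 and Gfap, a glial filament, at 0.22 and 0.68. None passed the threshold.

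The third comparison asked what separates the phases. Between day 14 and day 7 no single transcript passed. Lists of myelin and collagen transcripts and some immune lists were higher at day 14 by camera with a preset correlation. The myelinating Schwann cell list was higher by a mean of 0.25, with 18 of 18 members above day 7 (camera adjusted p = 9.6e-08, lost at an adjusted p = 0.559 with an estimated correlation). Pllp (0.57), Mal (0.47), Fa2h (0.28) and Pmp22 (0.12) were among the 8 members past the threshold adjusted over the list alone, against 0 over all genes tested. The extracellular matrix and fibroblast list was higher by 0.18 in 33 of 36 members (adjusted p = 7.7e-08, lost at an adjusted p = 0.559 with an estimated correlation). Its collagens Col1a1 (0.63), Col4a2 (0.41) and Col1a2 (0.34) and the crosslinking enzyme Lox (0.48) were among 6 members past the threshold adjusted over the list alone.

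Some immune lists were higher at day 14 than at day 7 as well. The interferon response list (mean 0.003, camera adjusted p = 0.867) and the lymphocyte list (mean 0.08, camera adjusted p = 0.084) did not pass. The macrophage list differed by 0.25 in 24 of 26 members (adjusted p = 9.8e-06, lost at an adjusted p = 0.632 with an estimated correlation), with Clec10a at 0.61, Cybb at 0.59, Laptm5 at 0.49 and Fcgr1a at 0.29. The cytokine, chemokine and complement list differed by 0.15 in 26 of 28 members (adjusted p = 1.4e-04, lost at an adjusted p = 0.249 with an estimated correlation), with Ccl7 at 0.38, Cntf at 0.33, C1s at 0.26 and Ccl5 at 0.22. The MHC list differed by 0.27 in 15 of 21 members (adjusted p = 0.024, lost at an adjusted p = 0.659 with an estimated correlation). Its members went both ways, with RT1-Bb at 1.48 and RT1-Ba at 1.46 but RT1-T24-4 at -1.04, and another RT1-Ba probe set stood at -1.10. The circadian clock list was lower by -0.18 in 13 of 17 members (adjusted p = 0.024, lost at an adjusted p = 0.559 with an estimated correlation), with Per2 at -0.82, Tef at -0.28, Cry1 at -0.26 and Cry2 at -0.21. Other probe sets went the opposite way for Per2 (0.08) and Cry2 (0.06). As many as the 6 lists were called in 65 of 100 splits of the same arrays, the real one included.

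**Figure D2:**
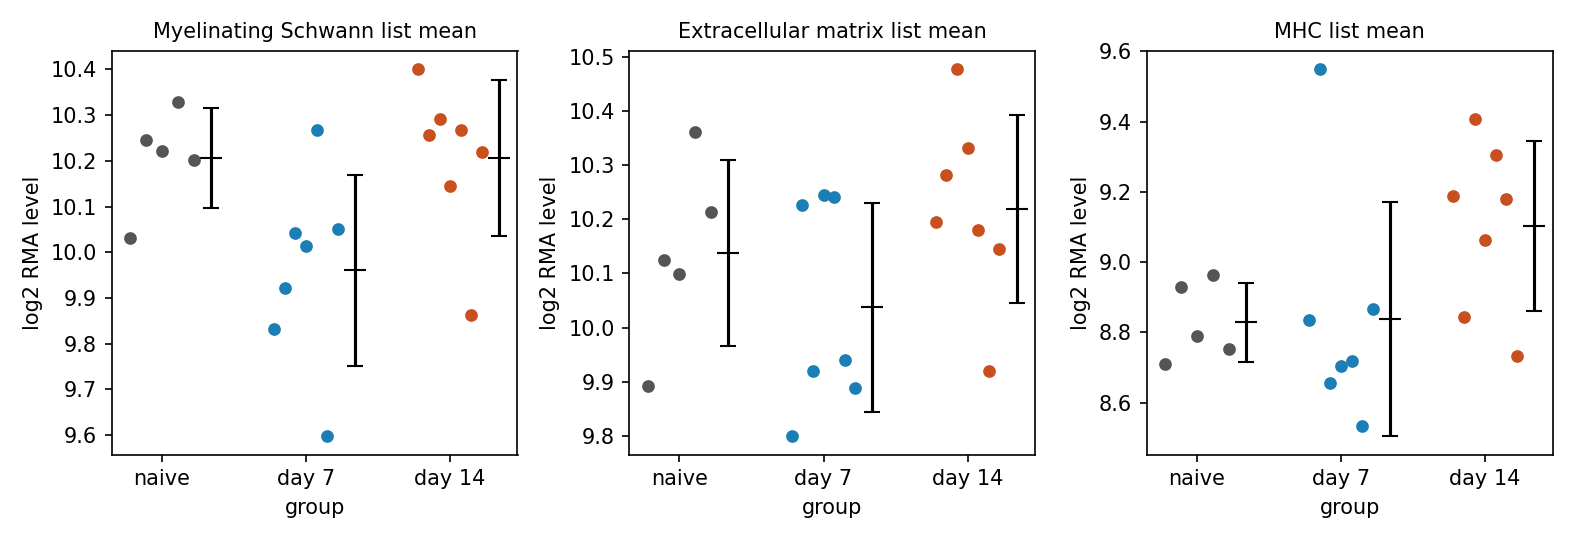
Mean log2 RMA level (vertical axes) of the myelinating Schwann cell, extracellular matrix and fibroblast, and MHC lists on each array (points) of the naive, day 7 and day 14 groups, with the group mean and SD (bars). The myelinating Schwann cell mean is 10.21 ± 0.11 in naive rats, 9.96 ± 0.21 at day 7 and 10.21 ± 0.17 at day 14.

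With limma, 0 of 31042 probe sets passed between day 14 and day 7, with 3516 at an unadjusted p under 0.05 and a smallest adjusted p of 0.133. The smallest p belonged to Sstr1 at -0.38. The other falls of smallest p, in order of size, were Nrcam at -0.59, Kcnj5 at -0.46, Ift70a1 at -0.35 and Slc4a1ap at -0.23. The rises of smallest p were Col1a1, Spon2 (0.59), Afg3l1 (0.43), Tead1 (0.36) and Zc3h14 (0.24). Other probe sets went the opposite way for Sstr1 (0.09 and 0.10), Kcnj5 (0.20), Zc3h14 (-0.01 and -0.09) and 1 of Nrcam (0.39). Bdnf differed by 0.04 ± 0.15 (SE), Atf3 by 0.74 ± 0.56 and Npy by 0.49 ± 0.71, all within the spread between rats. A test of any difference among the 3 groups passed 8 probe sets.

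Both operated groups were set against the same naive arrays, and their differences from naive correlated across probe sets with r = 0.70. Simulations of unchanged groups against shared controls gave a mean r of 0.58, with a highest of 0.81. The covariance was 0.0150 against a simulated mean of 0.0074 and a highest of 0.0145 in 100 simulations. Probe sets are not independent replicates. With the naive arrays split so that each comparison had its own controls, r averaged 0.26 and the covariance 0.0075. All 43 probe sets called at day 14 had the same sign at day 7, where simulations gave a mean of 41.4. At an unadjusted p under 0.05 and the same sign at day 7 were 6 of the 8 higher and 25 of the 35 lower, against 0.30 and 1.75 for independent lists. Simulations put this number at a mean of 22.7 and at most 43, against 31 observed.

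Of 30 exact permutation tests of array measures between groups, 0 passed after adjustment, and the smallest adjusted p was 0.133. An exact p under 0.05 was met by 4, of which 3 set day 14 against naive, the comparison with the 43 calls. These were principal component 3 (exact p = 0.010), principal component 1 (exact p = 0.014) and the interquartile range of the array (exact p = 0.018), and the other was the central nervous system list between day 14 and day 7 (exact p = 0.015). The 3' minus 5' signal of control transcripts was 3.42 ± 0.18 (SD, n = 5) in naive rats, 3.27 ± 0.08 (SD, n = 7) at day 7 and 3.26 ± 0.07 (SD, n = 7) at day 14. Its exact permutation p, two-sided, was 0.081 at day 7 and 0.054 at day 14 against naive, and for Gapdh alone 0.039 at day 14 (adjusted p = 0.235). The skeletal muscle list averaged 6.68 ± 1.07 (SD, n = 5), 6.66 ± 0.78 (SD, n = 7) and 6.39 ± 0.46 (SD, n = 7) in the 3 groups, and exact permutation p values for it were 0.956 at day 7 and 0.604 at day 14. With the 3 arrays high in muscle transcripts left out, a choice made after seeing the data, 12 probe sets passed at day 14, and 131 with the muscle list mean as a covariate.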

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

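All tests of explanations in this part were chosen after the results were seen, except the splits of the arrays, the held-out position of arrays by code prefix and the joint movement of myelin and matrix lists. How far the held-out positions had to clear those of naive arrays was also settled after their values were seen. Of 330 groups of values examined for a highest or lowest array far from its neighbour for the group's range (Dixon's test), 22 had one, where chance gives about 1 in 20, or 16.5.

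Skeletal muscle list means stood apart on 1 array per group, at 8.59 on naive replicate 1 (next 6.37), 8.31 on day 7 replicate 7 (next 6.82) and 7.43 on day 14 replicate 2 (next 6.27). Day 7 replicate 2 was the highest of its group for the MHC list mean (9.55), the cytokine, chemokine and complement list mean (7.20) and Jun (11.31). Day 7 replicate 4 was the highest for the adipocyte list mean (7.67) and the lowest for Sox10 (8.38), and day 7 replicate 6 the lowest for Bcas1 (9.60) and the highest for Slc4a1ap (8.54). Among naive arrays, the highest values were Jun at 10.94 and Cntf at 11.29 on replicate 2, Ndufb8 at 8.58 on replicate 3 and Nrcam at 8.73 on replicate 4, and the lowest was Cdh2 at 9.33 on replicate 3. The remaining single arrays were low for Abca8a (11.89, day 7 replicate 1) and Tef (9.26, day 7 replicate 3), and at day 14 low for Col1a2 (11.67, replicate 6), Copz1 (7.09, replicate 1), Ntrk2 (10.88, replicate 3) and Bbs5 (6.17, replicate 5), and high for Nrcam (8.43, replicate 3).

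The effects at day 7 and day 14 differed for 6 lists by camera with a preset correlation. They differed for 0 with an estimated correlation (smallest adjusted p = 0.249) and for 0 by the exact permutation test of list means. Exact adjusted p values of the 6 lists ran from 0.152 to 0.447. The smallest over all lists, 0.087, belonged to satellite glia, which camera did not call. Day 14 lay above day 7 by a mean of 0.25 for the myelinating Schwann cell list, 0.25 for macrophage, 0.27 for MHC, 0.15 for cytokine, chemokine and complement, and 0.18 for extracellular matrix and fibroblast, and stood at -0.18 for circadian clock.

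Nerve injury response genes varied strongly among operated rats: the list mean had a within-day SD of 0.463 in 14 operated rats against 0.065 in 5 naive rats. The SD in operated rats exceeded those of all 10000 random lists matched on mean level (percentile 100, highest 0.148), but random genes do not vary together, so that excess decides nothing. The naive SD of 0.065 is of the same genes, which argues against their ordinary spread between arrays, as far as 5 naive rats can show. Some other lists spread more among naive arrays, with SDs of 0.66 for the red blood cell and 1.07 for the skeletal muscle list. The latter rests largely on 1 array, at 8.59 (next 6.37). Skeletal muscle carried along is argued against as the whole cause: 11 of the 14 operated arrays had an injury list mean above every naive array by more than the naive SD, and their median muscle list mean was 6.23, as in naive arrays (6.23), although 4 of the 11 had more muscle (r over operated arrays centred by day = 0.045, permutation p = 0.890; rho = 0.16, p = 0.596; r = 0.20 without the 2 arrays farthest from the median; 0.27 within day 7 and -0.35 within day 14). RNA quality stays open, with 95% limits of -0.67 to 0.40 for the relation to the 3' to 5' signal (r = -0.20, permutation p = 0.517; rho = -0.22, p = 0.47; r = -0.50 without the 2 farthest arrays; 0.03 within day 7 and -0.44 within day 14). A candidate explanation is that some T11 axons were themselves injured in some rats, which was not tested and for which the labels give no measure.

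The 43 probe sets called at day 14 exceeded every other split. Of 100 splits of the same arrays, 1 gave as many, the real one, and the highest of the others called 1. Chance is thus an unlikely account of their number, as far as 100 splits can show. RNA quality, as the 3' to 5' signal measures it, is argued against as the whole cause. With that signal as a covariate the log2 differences kept a median ratio of 0.94 (lowest 0.67). All 43 kept their sign and had an unadjusted limma p under 0.05, although they were picked on the same arrays. A contribution of RNA quality stays open, because the covariate left 0 calls, with standard errors larger by a median factor of 1.17. When both AJ arrays of day 14 were held out, they lay at 0.54 and 0.69 between naive (0) and other day 14 arrays (1), above held-out naive arrays (0.20 to 0.37, SD 0.061; the AJ ones 0.24 and 0.29) by more than the spread, which argues against the cohort marked by the prefix as the whole cause. A contribution of it stays open, since at day 7 all 5 AJ arrays (0.32 to 0.49) lay above both AK arrays (0.22 and 0.27), the lower position at day 14 cleared the bound of 0.5 by less than the SD (held-out AI arrays 0.50 to 0.89), and the prefix as a block left 0 calls, with a median ratio of 0.92 and standard errors 1.58 times as large. Among AJ arrays alone, 2 naive and 2 at day 14, all 43 kept their sign with a median ratio of 0.94 (the calls were made with these arrays included), a split of 5 AI arrays against 7 others called 0 probe sets, and response to denervation itself remains among the open explanations.

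The myelinating Schwann cell list was lower at day 7 than at day 14 by camera with a preset correlation. The call was lost with an estimated correlation (adjusted p = 0.559) and by the exact permutation test (p = 0.031, adjusted 0.236). The 3' to 5' signal hardly differed between day 14 (3.26 ± 0.07, SD, n = 7) and day 7 (3.27 ± 0.08, SD, n = 7), with an exact permutation p of 0.797. This argues against RNA quality, as that signal measures it, as the cause. The list mean was 0.25 with the signal as a covariate, which could hardly move a comparison of groups with nearly equal signal. Aspects of RNA quality that the signal misses stay open. Less Schwann cell and connective tissue in the day 7 ganglia stays possible. Over 19 arrays centred by group the myelin and matrix list means moved together (r = 0.580, permutation p = 0.016, adjusted over 4 relations 0.065; rho = 0.49, p = 0.051, adjusted 0.202). Without the 2 farthest arrays r was 0.46, and r was 0.45 within day 7 and 0.64 within day 14. Centring removes the difference between the days, so this relation cannot show what separates them. A change in Schwann cells themselves between the days stays open. The cohort marked by the code prefix is argued against as the whole cause. The AK arrays had list means of 9.60 and 9.92 at day 7 but 10.20, 10.25 and 10.33 in naive rats. At day 14 the AJ arrays (10.14 and 10.29) lay within the range of the AI arrays (9.86 to 10.40). A contribution of the prefix stays open, since the AJ arrays of day 7 (9.83 to 10.27) overlapped those of day 14. Prefix AI occurred at day 14 alone, and no day 14 array had prefix AK.

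For other results the splits say less. At day 7 and between the days 0 probe sets were called, which all 100 of 100 splits reach by construction, so these counts test nothing (highest others 7 and 1). The 8 probe sets of the test of any group were met in 1 of 100 (highest other 4), so chance is an unlikely account of their number. For lists, chance was not excluded: 94 of 100 splits called at least the 4 lists of day 7 (highest other 18), 78 at least the 5 of day 14 (highest other 17) and 65 at least the 6 between the days (highest other 20). The median of the other splits was 8, 7 and 7 lists, above each real number, which points to correlated genes within lists on these arrays.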

How the results depend on the processing

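The settings with muscle transcripts and the exact test of list means were chosen after seeing the data; all others were planned, and the cause of each change was not tested unless fewer arrays or genes tested give it. The 43 probe sets of day 14 became 28 with quantile normalization again, 76 with array weights, 13 with only the compared groups in the fit, 20 with 1 probe set per gene, 14 with the mean of a gene's probe sets, 0 with the animal code block, 0 with the RNA 3' to 5' covariate, 4 adjusted over all comparisons together, 729 at an adjusted p under 0.1, 102 at an unadjusted p under 0.01 with a fold of 1.5, 12 without 3 arrays with muscle transcripts and 131 with the muscle covariate. It was 41 without the 33.3% dimmest probe sets, where signal over background is least, 36 with median centring and 35 with trend and robust moderation. The 8 of any group became 18 without the dimmest, 24 with array weights, 45 at an adjusted p under 0.1, 1 with the RNA covariate, and 0 with 1 probe set per gene, a gene's mean, the code block or without the 3 arrays. The 0 of day 7 became 2 with the RNA covariate and 33 at the looser p and fold, and the 0 between the days became 1 with the code block and 27 at the looser p and fold. Leaving out each array gave 5 to 401 for day 14 (65 and 401 without day 14 replicate 1 and naive replicate 1, 28, 5 and 15 without naive replicates 2, 3 and 5, and 26, 6 and 16 without day 14 replicates 2, 5 and 6), 0 to 2 for day 7 (2 without naive replicate 4 or day 7 replicate 6), 0 to 2 between the days (2 without day 7 replicate 1) and 0 to 18 for any group (15 and 18 without naive replicate 4 and day 14 replicate 4, and 0 without naive replicate 5 or day 14 replicates 2 or 5). Bdnf at day 14 ranged from 0.58 to 0.93.

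Lists past camera, 4, 5 and 6 in the 3 comparisons, became 0, 0 and 0 with an estimated correlation, 0, 2 and 0 with fry and 0, 0 and 0 with the exact permutation test of list means. At day 14 they became 9 without the dimmest probe sets and 11 each with the code block and RNA covariate; between the days 11 without the dimmest and 10 each with array weights and the code block. Leaving out each array gave 2 to 7 (2 without day 7 replicates 6 or 7, 7 without 2), 4 to 9 (8 and 9 without naive replicates 2 and 4) and 4 to 12 (12 and 10 without day 7 replicates 2 and 7, 11 without day 14 replicate 3). The oxidative phosphorylation mean at day 7 turned to -0.012 with the RNA covariate (adjusted p = 0.795). The r of 0.70 between differences became 0.26 with split controls and 0.66 to 0.76 without each array; array quality tests stayed at 0 past the threshold. The labels give no pairing of rats by replicate number. The 17 same-numbered pairs had r from -0.26 to 0.33, 3 over 0.1, with a mean of -0.031 against 0.005 for other pairs. Of 19 arrays, 5 correlated best with their own number, which was not tested against chance. With the replicate block 9 probe sets passed at day 14 and 0 for any group, and 2 and 8 lists passed at day 7 and day 14.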

Other observations

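The lists for genes of cilia and ribosomal RNA processing, the exact tests of list means and the relation of Bdnf to the injury list were chosen after the results were seen. Of the lists that missed camera, 2 had small exact p values at day 14, neither past the threshold after adjustment. At day 14 the satellite glia list mean was 10.17 ± 0.04 (SD, n = 7) against 10.05 ± 0.09 (SD, n = 5) in naive rats, with an exact permutation p of 0.0088 and 0.066 after adjustment over 30 lists. The peptidergic nociceptor list mean was 9.27 ± 0.07 (SD, n = 7) against 9.17 ± 0.06 (SD, n = 5), with an exact permutation p of 0.023 and 0.136 adjusted. Within that list, named here after their values were seen and adjusted over the list alone, Calcb (0.31), a pain-related peptide, and Kit (0.28) were higher and Trpv1 (-0.18), the capsaicin receptor, was lower. The smallest exact adjusted p at day 14, 0.057, was shared by the repair Schwann cell list, with 7 of 7 arrays above every naive array, and the cytokine, chemokine and complement list, with 6 of 7.

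The largest called difference at day 14 belonged to an unnamed probe set, at 2.22 log2 units, chosen here after its values were seen. It was above 7 on 6 of 7 day 14 arrays, 1 of 7 day 7 arrays and 0 of 5 naive arrays, and no array lay between 5.59 and 7.24. Its gene is not named here, so no explanation was tested.

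Falling calls at day 14 included 4 genes of cilia, Bbs4, Bbs5, Ift70a1 and Kifap3. The hypothesis that transcripts of intraflagellar transport and the BBSome, complexes that move cargo in the primary cilium, are lower as a set was tested on the 34 measured members that were not called. They averaged -0.11 log2 units, with 28 of 34 below naive, and camera gave p = 1.9e-05, or p = 0.0067 with an estimated correlation. Splits of the naive and day 14 arrays gave a p as small in 3 of 100 cases, the real one included, the smallest other being 4.3e-06, and 49 of the 99 others gave a camera p under 0.05. Because the set was picked from calls of the real split, chance is not excluded. Day 7 averaged -0.03 against naive (camera p = 0.209, and 0.374 with an estimated correlation), and day 14 against day 7 averaged -0.07 (camera p = 8.2e-06, and 0.0050 with an estimated correlation). That the cilium set may be lower at day 14 remains an undecided hypothesis, found and tested on the same arrays, with code prefix and RNA quality open too.

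For ribosomal RNA processing the same test did not pass at day 14. Beside the called genes Utp18, Wdr75, Mphosph10 and Tgs1, the 37 other measured members of the small subunit processome list averaged -0.01 at day 14, with 18 below naive (camera p = 0.525, and 0.673 with an estimated correlation). Between day 14 and day 7 the mean was -0.03 (camera p = 0.032, and 0.167 with an estimated correlation).

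Whether Bdnf follows the injury response of each rat could not be decided. Over 14 operated arrays centred by day, Bdnf and the nerve injury list mean had r = 0.339 (permutation p = 0.253; adjusted over 4 relations 0.506) and rho = 0.43 (p = 0.144; adjusted 0.287). Without the 2 arrays farthest from the median r was 0.69, and r was 0.86 within day 7 but -0.24 within day 14.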
